A study of Mus musculus with 17 samples.

How the data were processed

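RNA had been sequenced from non-tumorous liver of 17 male C57BL/6J mice aged 32 weeks, 1 library per mouse, in 3 groups taken from the sample titles and treatment labels. The groups were 5 mice on a regular diet, 6 vehicle mice and 6 mice given a monoclonal antibody against claudin-1 (CLDN1). Vehicle and antibody mice had both received the carcinogen diethylnitrosamine (DEN) and CDA-HFD, a choline-deficient, amino acid-defined high-fat diet.

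The deposited table held a signal per gene and library, counts normalized by the authors with cuffnorm per the labels of the deposited table, made with Cufflinks 2.2.1 on mouse build mm10 per the submitters' processing notes. The aligner, the annotation release, the strand setting and the scaling option were not given in the sources used here. The values were not raw counts and did not add up to a fixed total per library. In each library 97.7 to 98.2% of the low values, those up to 20 steps, lay within 0.05 of a step of a whole multiple of 1 step, which was taken as the worth of 1 fragment. Dividing the deposited total by that step gave the estimated fragments per library, from 27.7 to 59.5 M. Very small values in place of 0 and failed estimates kept the fragments of every gene from being recovered, so no count model was used as the main test.

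The table held 52545 genes, of which 17421 were at 0 in all libraries. Symbols were found for 52398 gene identifiers (99.7%), and coordinates, lengths and overlaps came from a GENCODE annotation of the same mouse build. An exact 0 in this table can be a failed estimate. Alb, the albumin gene, was listed at 0 in all 17 libraries, and 141 genes had a value under 0.1 in a library while a library of the same group was at 100 or more. Strand was not stated, so antisense genes, overlapping genes and members of near-identical families (Mup, Cyp2c, Cyp2b, Serpina1, Saa and H2 genes, for example) were treated as uncertain.

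Genes with a value of at least 10 in 5 or more libraries were tested (18624 genes). Values were taken as log2(value + 1), a scale that understates the change of low genes, and a limma-trend model (limma 3.58.1 in R 4.3.3) was fitted to all 17 libraries with group as the only term. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Every adjusted p of a gene below is from this limma fit unless another is named, and every fold change is on the log2(value + 1) scale. Values are normalized counts given as mean ± SD. The p-values measure the spread between these mice.

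The tests, 49 gene lists, the rule for the genes named and most alternatives were fixed before the data were examined. The lists covered matrix and fibrosis, signalling pathways, lipid, bile acid, one-carbon and drug metabolism, stress responses, sex-biased genes, the clock, and markers of the cell types and neighbouring tissues that a piece of liver could hold. They were tested with camera (limma) at a preset inter-gene correlation of 0.01, and set beside camera with an estimated correlation and fry's directional p, each adjusted over the 49 lists. Camera compares a list with all other genes, whereas fry asks only whether the list members changed. Genes named were a panel of liver disease genes, the 8 genes with the largest fold change in each direction among those past the threshold with a mean of at least 50 and no overlap between groups (or, where none passed, the 5 with the smallest p in each direction), and up to 3 members of each list with the smallest p, with a member of the opposite direction where one passed. The 8 and the 5 genes per direction had a mean of at least 50 in the higher group. Unnamed gene models, microRNA and snoRNA genes, and immunoglobulin or T cell receptor segments were left out of these picks. H19, Igf2 and the further Mup genes were chosen after their values were seen.

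The position of each library on the line from the regular diet mean (0) to the mean of all 12 vehicle and antibody mice (1) was compared between groups with a two-sided exact permutation test, as were other single values. To ask whether the antibody group lay nearer to the regular diet group, the covariance across genes of the effects of the model and of the antibody was computed with the 6 vehicle libraries split between both comparisons, over all 20 splits, with an exact test over 924 regroupings of vehicle and antibody mice. A covariance from shared vehicle libraries alone was simulated in 100 draws.

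The procedure was tested on simulated values for the 18624 genes, with 200 changed genes per comparison. For antibody against vehicle it recovered 7.46% of genes changed 1.5-fold, 38.8% of those changed 2-fold and 81.8% of those changed 4-fold, with 6 false calls. For vehicle against regular diet, the shares were 11.9%, 25.4% and 56.1%, with 4 false calls. For antibody against regular diet they were 5.97%, 31.3% and 68.2%, with 5. Each comparison had a single draw, in which genes varied independently of each other. Genes of real libraries vary together, and 9400 rather than 200 genes changed between vehicle and regular diet. The recoveries and false calls therefore describe the simulated values and set no rate for these data.

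Alternatives covered the pseudocount, the filter, quantile and total scaling, the groups in the fit, library weights, robust moderation, a 2-fold minimum, a replicate block, a term for the library code, other set tests, and each library left out. Voom on the estimated fragments and a test without the genes with failed estimates were added after seeing the data, as were total scaling for the lists and for the covariance and the omission of vehicle libraries for the covariance. The mitochondrial share was not used, because mt-Co1 had failed estimates. Figures were drawn with matplotlib.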

Results

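The series asked how an antibody against claudin-1, a tight junction protein that is also exposed on liver cells outside junctions, changes gene expression in a mouse model of fatty liver disease with fibrosis and liver cancer. Non-tumorous liver was profiled in 17 male C57BL/6J mice at 32 weeks of age. The 5 regular diet mice served as the untreated reference. The 6 vehicle mice had received 100 mg/kg of DEN, a liver carcinogen, in week 1, CDA-HFD as their diet, and 1 intraperitoneal injection of PBS per week for 16 weeks. The 6 antibody mice were treated alike, except that 500 µg of CLDN1 antibody was injected per week in place of PBS. Carcinogen, diet and injections were given together, so their effects against regular diet cannot be separated.

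Depth, estimated from the step between low values, was 38.6 ± 9.6 M fragments per library in regular diet (SD, n = 5), 48.5 ± 8.19 in vehicle (n = 6) and 41.6 ± 9.57 in antibody (n = 6), and did not differ detectably between antibody and vehicle (two-sided exact permutation p = 0.214). The deposited totals were 54.8 ± 11.2, 35.4 ± 5.53 and 39.9 ± 3.43 M. Every regular diet library stood above every vehicle library in that total, and regular diet replicate 1 was highest at 74.6 M. The first principal component, with 56.7% of the variance, placed regular diet between -153 and -121 and all other libraries between 12 and 112.

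Many single genes of scar tissue, immune cells, bile ducts and proliferation were higher in vehicle than in regular diet livers, and many of hepatocyte metabolism were lower. Of 49 gene lists, 33 passed camera at the preset correlation. All 33 also passed fry (adjusted p at most 0.0021), which does not compare a list with other genes and passed 38 of the 49 lists. With an estimated correlation 0 of 49 passed (smallest adjusted p = 0.202). Lists of this comparison given below with only the estimated correlation are among the 33. Col1a1, the main fibrillar collagen gene (chromosome 11, 94936224 to 94953042), rose from 230 ± 76.6 to 8060 ± 3190 normalized counts, a log2 fold change of 5.04 ± 0.37 (SE; adjusted p = 8.77e-09). Gpnmb, a glycoprotein gene of lipid-laden macrophages (chromosome 6, 49036546 to 49070929), rose from 100 ± 53.7 to 64300 ± 44500 (log2 fold change 9.01). Scd1, which encodes the main fatty acid desaturase of liver, fell from 574000 ± 202000 to 13500 ± 9310 (log2 fold change -5.65). Of 18624 genes tested, 9400 changed, 5547 of them higher and 3853 lower, and 4354 and 1927 changed at least 2-fold.

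Among 32 fibrillar collagens and matrix proteins, 29 rose, 2 fell and 1 did not pass (camera adjusted p = 3.21e-09; adjusted p = 0.265 with an estimated correlation). Col1a2 rose by a log2 fold change of 4.32 and Col3a1 by 3.93, while Col5a3 fell (-1.72). Of 24 matrix remodelling enzymes and inhibitors, 23 rose and Mmp19 fell (-1.02; list adjusted p = 0.265 with an estimated correlation), though Mmp19 not with the same total per library (adjusted p = 0.298). They included Mmp12, the macrophage elastase, at 38400 ± 21500 against 81.3 ± 32.6 (log2 fold change 8.73), Timp1 (6.21), the tissue inhibitor of metalloproteinases, and Lox (4.35), which crosslinks collagen. Acta2, the smooth muscle actin of myofibroblasts, stood at 540 ± 187 against 243 ± 196 and did not pass (adjusted p = 0.0585). Of 20 myofibroblast and portal fibroblast markers, 15 rose, Lum and Dpt among them (adjusted p = 0.363 with an estimated correlation). Hepatic stellate cell markers did not pass as a list (camera adjusted p = 0.192), with 9 of 20 higher, including Pdgfrb at 2.59.

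Of 21 TGF-beta pathway genes and targets 18 rose, with Itgb6 at 5.06 and Ltbp2 at 4.88, and of 25 genes of epithelial-mesenchymal transition 16 rose and 3 fell, with S100a4 at 4.62 (both adjusted p = 0.265 with an estimated correlation). Of 29 TNF and NF-kappaB targets 22 rose, including Tnf itself, from 9.61 ± 5.84 to 222 ± 28.9 (log2 fold change 4.56), while Sod2 fell by 1.11 (adjusted p = 0.218 with an estimated correlation). Of 22 YAP and TAZ targets 13 rose, Ankrd1 by 4.64 (adjusted p = 0.353 with an estimated correlation), and of 18 MAPK feedback targets 12 rose, Ccnd1 by 3.18, while Dusp1 fell by 1.68 (adjusted p = 0.265 with an estimated correlation). The Notch list did not pass (camera adjusted p = 0.192), although 10 of its 21 members rose, among them Sox9 at 1.91 and Hes1 at 0.65. The Hes1 call ended with quantile normalization (adjusted p = 0.0839) and with no filter (adjusted p = 0.072). It also ended with only the groups compared (adjusted p = 0.0546). Leaving out any of regular diet replicates 2, 3, 4 and 5 or vehicle replicates 1, 3, 4, 5 and 6 ended it too. The adjusted p was then from 0.0505 to 0.119, so the Hes1 call is weak.

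Immune cell markers were higher in nearly all lists tested. Of 23 markers of lipid- and scar-associated macrophages, 21 rose, with a list median of 4.75 and Trem2 at 6670 ± 3620 against 222 ± 49.9 (log2 fold change 4.69; list adjusted p = 0.252 with an estimated correlation). Pan-macrophage markers (17 of 19 higher), monocyte markers (14 of 15, Ccr2 at 4.18), T cell markers (23 of 26, Cd8a at 3.10), NK cell markers (17 of 18, Klrd1 at 3.55) and dendritic cell markers (16 of 18, Ccl22 at 5.05) rose as lists, each with an adjusted p = 0.265 with an estimated correlation. Neutrophil markers rose in 10 of 15, Clec4d by 6.91 (adjusted p = 0.355 with an estimated correlation). Kupffer cell markers went the opposite way, with 8 of 17 lower and 2 higher, Cd163 at -4.87 and Timd4 at -4.52 (adjusted p = 0.335 with an estimated correlation). Of 31 chemokines and receptors 25 rose, Ccl2 by 3.59, and Cxcl13 fell by 3.44 (adjusted p = 0.218 with an estimated correlation). Interferon-stimulated genes rose in 22 of 32, Oasl2 by 3.13, and antigen presentation genes in 14 of 17, H2-Aa by 2.63 (adjusted p = 0.265 and p = 0.324 with an estimated correlation). B cell and plasma cell markers did not pass (camera adjusted p = 0.23), with 3 of 23 higher, Cd22 by 2.43.

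Of 40 cell cycle genes 35 rose and none fell, Mki67 by 3.66, from 91.5 ± 31.8 to 1130 ± 240. The list had a camera adjusted p = 2.32e-16, a fry adjusted p = 1.55e-09 and an adjusted p = 0.202 with an estimated correlation. Of 28 liver tumour and fetal-liver genes 23 rose, with Ly6d at 6.63, Afp, the alpha-fetoprotein gene, at 2.05 and Gpc3 at 1.86 (adjusted p = 0.218 with an estimated correlation). Gpc3 did not pass with quantile normalization (adjusted p = 0.0922). Of 22 cholangiocyte and ductular reaction markers 19 rose, Spp1 (osteopontin) by 4.75 and Krt19 by 2.89 (adjusted p = 0.265 with an estimated correlation). The p53 and senescence list did not pass (camera adjusted p = 0.0607), though Cdkn1a, the cell cycle inhibitor p21, rose by 1.69. It was called higher with quantile normalization (adjusted p = 0.0179).

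Many hepatocyte metabolism genes fell. Of 24 genes of fatty acid and triglyceride synthesis 19 were lower and none higher, Fasn by a log2 fold change of -2.86 (adjusted p = 0.202 with an estimated correlation). Cholesterol synthesis genes fell in 14 of 25, Tm7sf2 by 2.75 (adjusted p = 0.304 with an estimated correlation). Urea cycle, amino acid and glucose genes fell in 25 of 28, G6pc among them (-4.13), choline, methionine and one-carbon genes in 21 of 32, with Gnmt at -3.80, bile acid genes in 19 of 25, with Cyp7b1 at -3.77, and xenobiotic cytochromes P450 in 15 of 26, with Cyp2c29 at -5.02 (each adjusted p = 0.265 with an estimated correlation). Exceptions rose, among them Pcyt1b (3.52), Abcc4 (2.52) and Cyp2b9 (6.98). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, did not pass (3660 ± 2410 against 4620 ± 1600; adjusted p = 0.32). Oxidative phosphorylation genes fell in 31 of 38 (adjusted p = 0.302 with an estimated correlation) and hepatocyte markers in 18 of 20 (adjusted p = 0.353 with an estimated correlation). The hepatocyte markers no longer passed after quantile normalization (camera adjusted p = 0.237). Fatty acid oxidation and PPAR-alpha targets fell in 16 of 29 and rose in 4, Fgf21 by 4.52 (camera adjusted p = 0.00206; adjusted p = 0.265 with an estimated correlation). The set test for that list turned its direction after quantile normalization (adjusted p = 0.984). With the same total per library all these lists stayed called, but their medians shrank, with a median shift of 0.62 over all genes. Examples were -0.98 to -0.36 for cholesterol synthesis, -0.94 to -0.32 for oxidative phosphorylation, -1.15 to -0.53 for xenobiotic cytochromes P450 and for one-carbon genes, and -0.71 to -0.09 for fatty acid oxidation.

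Among the lists without a call, acute phase proteins had 10 higher and 8 lower of 28, with Lcn2 at 5.82 (camera adjusted p = 0.929; called higher with quantile normalization, adjusted p = 0.00378). Lipid droplet and fatty acid uptake genes had 7 higher and 11 lower of 25, with Lpl at 3.74 and Cidec at 4.29; their median was -0.13, their mean was above 0, and the median turned to 0.18 after quantile normalization (camera adjusted p = 0.471). NRF2 targets (12 higher and 6 lower of 30, Nqo1 at 2.10) and integrated stress response genes (8 and 10 of 25, Psat1 at 4.39) had camera adjusted p-values of 0.451 and 0.545. With quantile normalization the NRF2 list was called higher (median 0.69 from 0.02; adjusted p = 3.01e-05), and the median of the stress response list turned from -0.17 to 0.45 with the same total per library. Immediate early and heat shock genes (7 higher and 6 lower of 25, Klf6 at 2.87) and endothelial cell markers (3 higher and 7 lower of 26, Cd34 at 2.96) did not pass either (camera adjusted p = 0.513 and camera adjusted p = 0.131). Both medians turned above 0 with the same total per library, where the set test called endothelial markers lower (adjusted p = 0.0189) against a median of 0.28. Claudins and tight junction genes had 9 higher and 7 lower of 26 (camera adjusted p = 0.586), with Cldn4 at 5.52. Cldn1, whose protein the antibody binds (chromosome 16, 26356642 to 26371841), was at 3990 ± 2490 in vehicle against 6830 ± 1400 in regular diet, a log2 fold change of -1.02 ± 0.38 (adjusted p = 0.0309), lower in 5 of 6 mice. That call for Cldn1 ended with the same total per library (-0.40; adjusted p = 0.335), with quantile normalization (-0.72; adjusted p = 0.127) and without any of 6 single libraries (adjusted p from 0.0513 to 0.0699), so it is weak.

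The largest changes also included Mmp7 (8.14), Vmn2r3, a vomeronasal receptor gene (8.01), and Sult1e1, estrogen sulfotransferase (7.77), among those higher. Among those lower were Moxd1 (-9.79; chromosome 10, 24223517 to 24302790), the male-biased steroid gene Hsd3b5 (-9.17), Dct (-7.97), Trhde (-7.18), Elovl3 (-6.89) and Slc13a2 (-6.02). Pitx3 (-7.44) overlaps Elovl3, and Hnf4aos (-5.71) overlaps Hnf4a, so their values were uncertain without strand. Mup14, Mup1 and Mup11 were listed at 0 in all regular diet libraries and at 1560 ± 1630, 833 ± 862 and 968 ± 1130 in vehicle. Mup3 (-5.40) and Mup21 (-4.06) fell. They start at 62083476 and 62147932 on chromosome 4, outside the span of the Mup genes at 0 (60066469 to 61674136). A 0 here can be a failed estimate, so no direction was read for the Mup genes at 0. In all, 49 tested genes were listed at 0 in every regular diet library. All 49 were called higher in vehicle and are counted among the 5547 higher genes, so that count includes calls that failed estimates could have made. A 0 throughout a group was not itself flagged as a failed estimate.

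**Figure D1:**
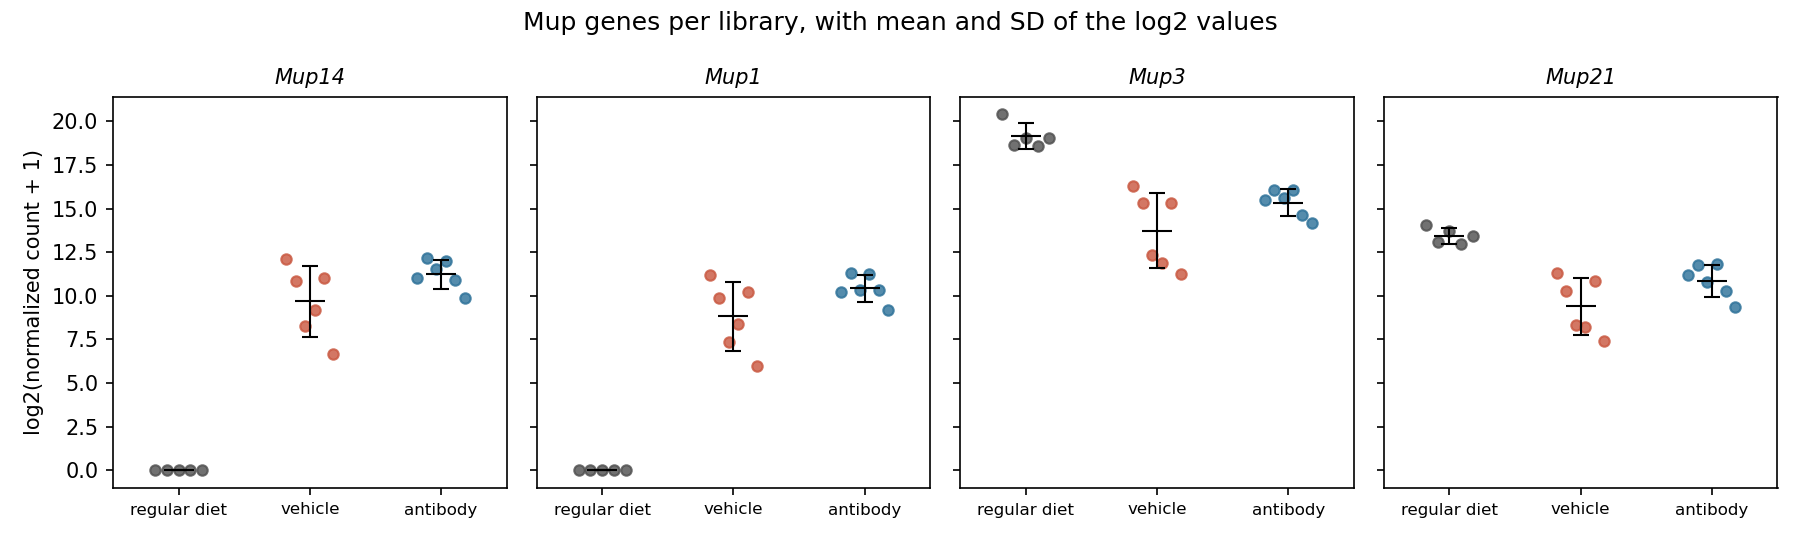
Normalized counts of 4 Mup genes on a log2(value + 1) axis. Each point is 1 library, and the black marks are the mean and SD of the log2 values per group. Mup14 and Mup1 lay at 0 in all regular diet libraries, and Mup3 and Mup21 had their highest means there.

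Counts of higher and lower genes rested on scaling. With the same total per library 9369 rose and 1264 fell, as all genes shifted by 0.62 on the log2 scale, and with quantile normalization 4447 rose and 5223 fell, with a shift of -0.44. The MAPK and neutrophil lists did not pass with the same total per library (adjusted p = 0.0512 and adjusted p = 0.0508). Of the 49 lists, 33 passed at the preset correlation, 0 with an estimated correlation (6 had an unadjusted p under 0.05) and 38 with fry, and 24 of 100 regroupings of these mice called as many lists, whereas no other regrouping called as many genes. Adjusted over the list alone, 870 list members passed. Regular diet libraries held library codes 31 to 35, between those of the other mice, so a step tied to codes 31 to 35 alone and the regular diet group cannot be told apart. A steady drift with the codes would not place regular diet outside both other blocks, which had mean positions of 0.956 and 1.04 (exact p = 0.301) on an axis with regular diet at 0.

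**Figure D2:**
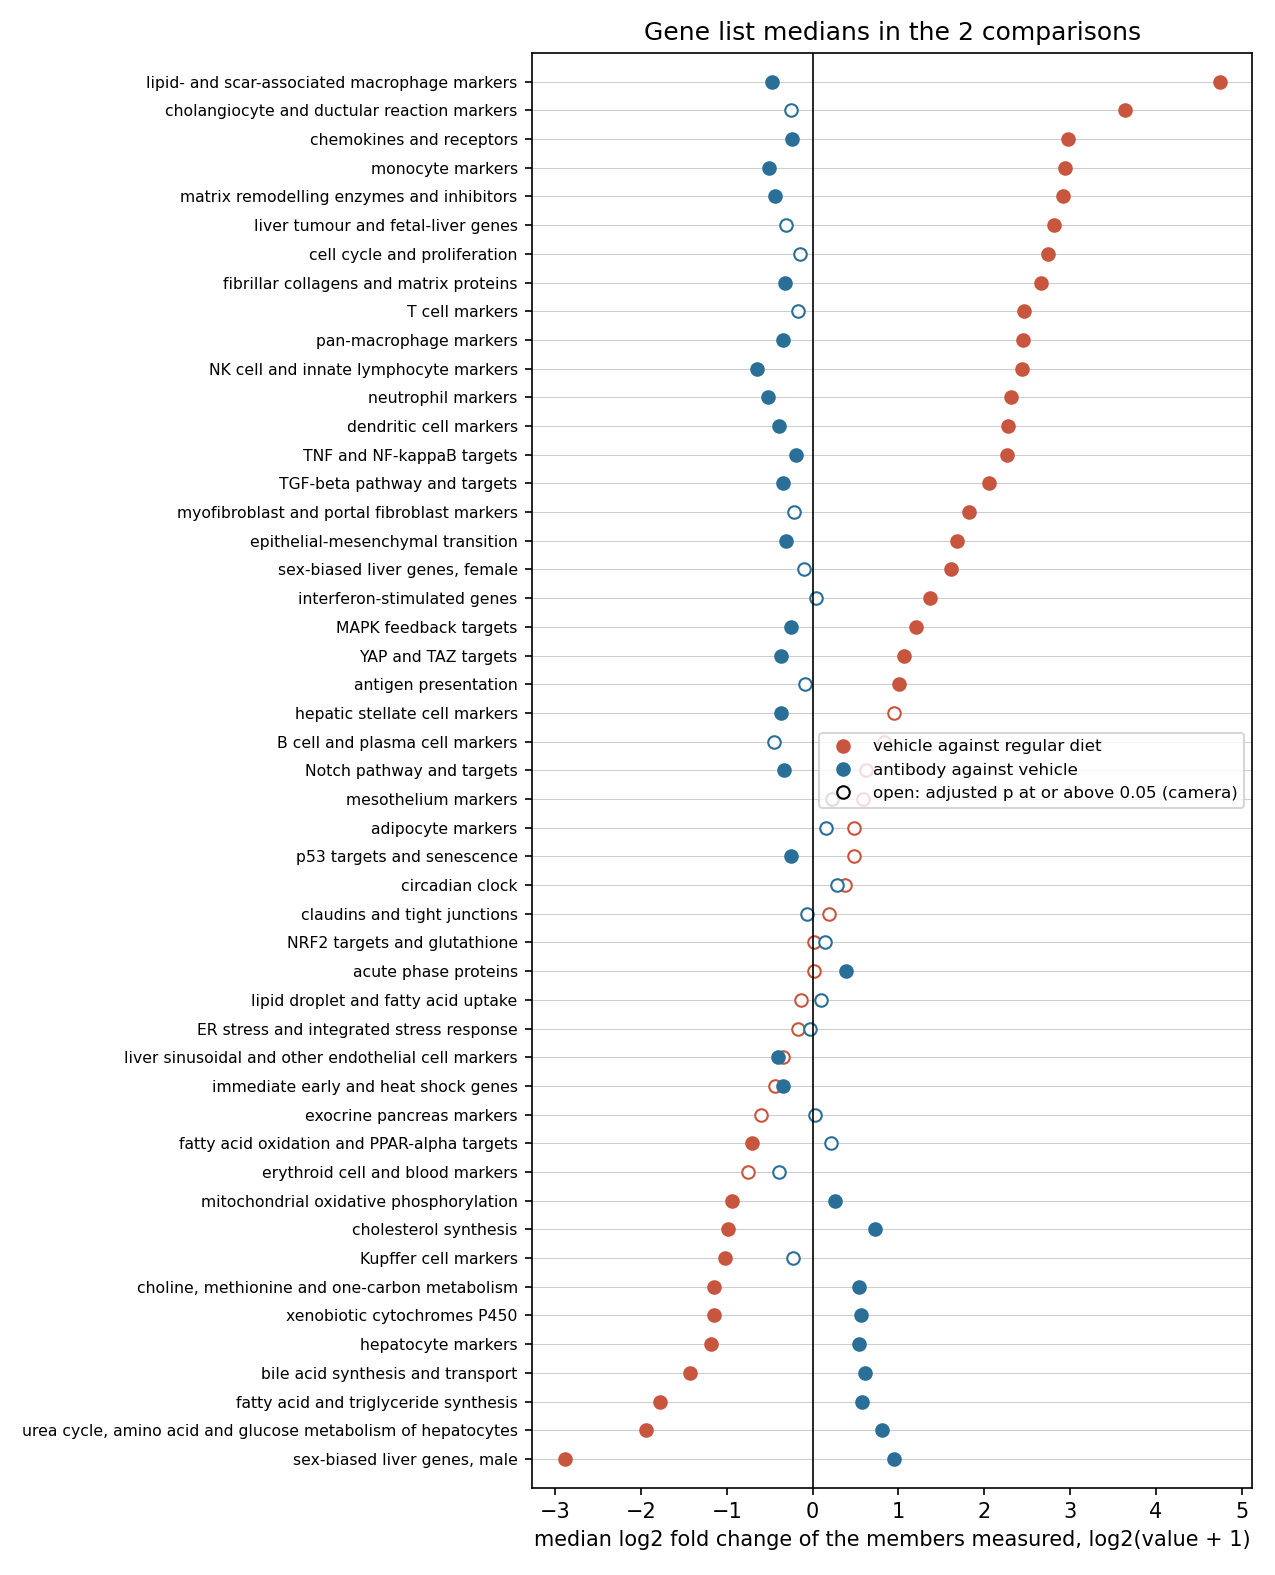
Median log2 fold change, on the log2(value + 1) scale, of the members measured of 49 gene lists, for vehicle against regular diet and for antibody against vehicle. Filled points passed camera at an adjusted p under 0.05 with the preset correlation, and open points did not. Medians ranged from -2.88 to 4.75 for vehicle against regular diet and from -0.65 to 0.95 for antibody against vehicle. With an estimated correlation no list passed in either comparison.

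The comparison of antibody with vehicle, which the series was built for, asked what the antibody changed in diseased liver. No gene passed the threshold. The genes given below for their smallest p are the smallest among those that the naming rule admitted. The smallest p-values among genes higher with antibody were those of Car5a, a mitochondrial carbonic anhydrase (chromosome 8, 121916126 to 121944904), at 1690 ± 471 against 683 ± 435 normalized counts (log2 fold change 1.51 ± 0.34, SE), and Fasn, fatty acid synthase, at 9330 ± 2830 against 5010 ± 722 (0.85 ± 0.19). Rbm12b2 had the smallest p among genes lower with antibody, at 212 ± 22.3 against 336 ± 44 (-0.65 ± 0.15). All 3 had an adjusted p = 0.659 and differed from the vehicle mean in the same direction in 6 of 6 antibody mice. They were picked by their p on these same mice, so the shared direction adds no support. Lists of cholesterol, fatty acid, bile acid and amino acid metabolism had medians above 0, and lists of matrix, macrophage and pathway target genes had medians below 0, but none passed with an estimated correlation or with fry.

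Of 25 cholesterol synthesis genes, 13 were higher when adjusted over the list alone and 0 over all genes tested, with a list median of 0.73 (camera adjusted p = 7.42e-20; adjusted p = 0.161 with an estimated correlation). Mvk, mevalonate kinase, was at 1580 ± 369 against 793 ± 356 (1.08). Fatty acid and triglyceride synthesis genes had a median of 0.57, with 10 of 24 higher adjusted over the list alone (adjusted p = 0.161 with an estimated correlation), among the members Acss2 (0.91) and Acacb (0.78). Urea cycle, amino acid and glucose genes had a median of 0.81, with 13 of 28 higher adjusted over the list alone (adjusted p = 0.27 with an estimated correlation), and Gpt differed by 0.80. The xenobiotic cytochrome P450 list (median 0.57, 3 of 26 adjusted over the list alone), the choline, methionine and one-carbon list (0.54, 5 of 32) and the bile acid list (0.61, 0 of 25) also passed camera, with an adjusted p = 0.161, p = 0.273 and p = 0.213 with an estimated correlation. Cyp1a2 was at 25500 ± 6420 against 12400 ± 4670 (1.09), Sardh at 25300 ± 4370 against 13300 ± 6070 (1.04), and Cyp27a1 at 13700 ± 2790 against 8040 ± 2680 (0.81). Oxidative phosphorylation genes (0.26), hepatocyte markers (0.54) and acute phase proteins (0.39) passed camera as well, with an adjusted p = 0.511, p = 0.511 and p = 0.559 with an estimated correlation.

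Lower medians were found for matrix remodelling enzymes (-0.44), collagens and matrix proteins (-0.32), TGF-beta targets (-0.35), YAP and TAZ targets (-0.37), the Notch list (-0.34) and epithelial-mesenchymal transition (-0.31). All passed camera at the preset correlation, with an adjusted p = 0.635 for collagens and p = 0.511 for the others with an estimated correlation. Ctsk, cathepsin K, was at 939 ± 216 against 3670 ± 3280 (-1.30), Ccn2, connective tissue growth factor, at 912 ± 255 against 2310 ± 1610 (-1.10), Hes1 at 723 ± 237 against 1070 ± 282 (-0.59) and Sox9 at 1020 ± 373 against 1440 ± 149 (-0.56). Col1a1 was at 6330 ± 2670 against 8060 ± 3190 (-0.28 ± 0.35; adjusted p = 0.826) and Timp1 at 684 ± 225 against 767 ± 134 (-0.21 ± 0.34; adjusted p = 0.873). MAPK feedback (-0.26), TNF and NF-kappaB (-0.19), p53 (-0.25) and immediate early genes (-0.34) also passed camera (each adjusted p = 0.511 with an estimated correlation), with Dusp1 at 686 ± 142 against 1790 ± 1080 (-1.21), Ier3 at -0.75 and Cdkn1a at 961 ± 250 against 1500 ± 198 (-0.68).

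Markers of lipid- and scar-associated macrophages had a median of -0.47, monocytes -0.51, NK cells -0.65, neutrophils -0.52, dendritic cells -0.40, pan-macrophage markers -0.35, hepatic stellate cells -0.36, endothelial cells -0.41 and chemokines -0.24. All passed camera, with an adjusted p from 0.511 to 0.635 with an estimated correlation. Trem2 was at 4070 ± 301 against 6670 ± 3620 (-0.47; adjusted p = 0.712), Cd63 at 4450 ± 991 against 7510 ± 3110 (-0.68), Ccr2 at 1300 ± 267 against 2120 ± 975 (-0.61) and Ifitm6 at 31.5 ± 10.3 against 62.8 ± 16 (-0.98). Lists that did not pass camera were cell cycle (adjusted p = 0.14, Mki67 -0.41 ± 0.21), liver tumour and fetal-liver genes (0.0501, Afp 0.12 ± 0.35), cholangiocytes (0.0598), myofibroblasts (0.384), T cells (0.351), B cells (0.0649), Kupffer cells (0.219), interferon-stimulated genes (0.13), antigen presentation (0.9), fatty acid oxidation (0.0725), lipid droplets (0.86), NRF2 targets (0.0514), the integrated stress response (0.384) and claudins (0.765). The median of the claudin list lay below 0 and its set test above. Lipid droplet genes differed in sign between median and mean. The medians of the fatty acid oxidation list (quantile normalization), of the interferon and lipid droplet lists (same total per library) and of the NRF2 list (both) turned below 0. With the same total per library, collagens, epithelial-mesenchymal transition, MAPK feedback, stellate, endothelial and neutrophil lists no longer passed (adjusted p from 0.055 to 0.11), and acute phase proteins no longer passed with quantile normalization (0.181). Lower calls were gained for cell cycle genes with the same total per library (adjusted p = 0.0214) and with quantile normalization for liver tumour genes (0.0258), cholangiocytes (0.0233), antigen presentation (0.0258) and the stress response (0.00653). Cldn1 was at 4060 ± 918 against 3990 ± 2490 (adjusted p = 0.844). Cyp7a1 was at 6110 ± 3320 against 3660 ± 2410 (0.91 ± 0.45).

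Further genes with the smallest p were Tiam2 (0.80), Ces2a (0.73) and Atg9a (0.56), higher, and Rbm24 (-2.43), Cfap161 (-1.46) and Ddit4 (-0.68), lower, with adjusted p = 0.659. Rbm24 and Cfap161 were listed at 0 in all regular diet libraries. By limma-trend 0 genes passed, 1391 had an unadjusted p under 0.05 where 931 were expected, and voom on the estimated fragments also called 0, with 1817 unadjusted. The unadjusted count was 3179 without vehicle replicate 1, 2242 without vehicle replicate 2, and 741, 680 and 758 without vehicle replicates 3, 4 and 6, and 849 and 811 without antibody replicates 3 and 4. With library weights, 5310 genes passed, 2512 higher and 2798 lower, but 8 of 100 regroupings of these mice called as many with such weights. Of the lists, 29 passed camera (10 higher, 19 lower), 0 passed with an estimated correlation (6 had an unadjusted p under 0.05) and 0 with fry (smallest adjusted p = 0.0865), and 32 of 100 regroupings called as many.

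**Figure D3:**
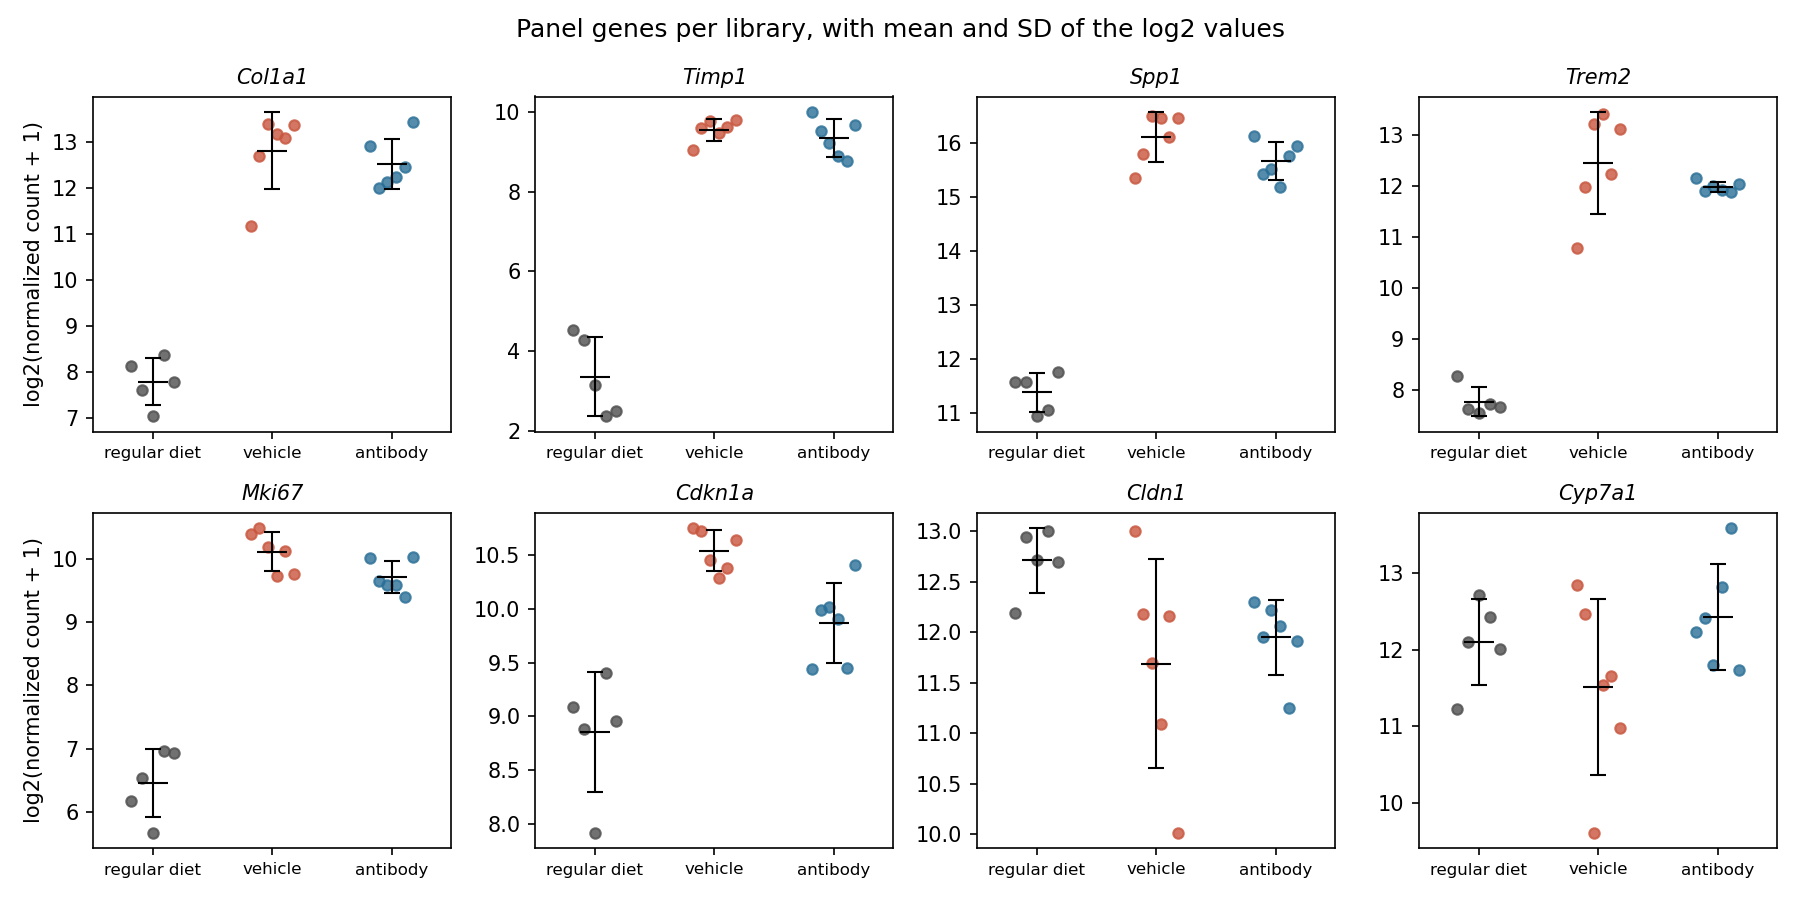
Normalized counts of 8 panel genes on a log2(value + 1) axis, by group. Each point is 1 library, and the black marks are the mean and SD of the log2 values. Vehicle and antibody libraries overlapped for all 8 genes, and Col1a1, Timp1, Spp1, Trem2, Mki67 and Cdkn1a lay above regular diet in both.

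Whether the antibody group lay nearer to regular diet was asked over all genes at once. On an axis with 0 at the regular diet mean and 1 at the mean of all 12 vehicle and antibody mice, antibody mice had a mean position of 0.934 ± 0.0782 and vehicle mice 1.07 ± 0.18, a difference of -0.131 (two-sided exact permutation p = 0.134). Vehicle replicates 3, 4 and 6 lay at 1.22, 1.22 and 1.23, above all antibody mice (0.828 to 1.03). Vehicle replicates 1, 2 and 5, at 0.819, 0.935 and 0.967, lay among or below the antibody mice. The lower antibody mean thus rested on vehicle replicates 3, 4 and 6. Within the libraries with codes up to 30 the difference was -0.0713 (exact p = 0.8), and within those with codes from 36 it was -0.192 (exact p = 0.3), where 3 mice against 3 cannot give an exact p below 0.1. The covariance across genes of the model and antibody effects, with vehicle mice split between them, was -0.258 (two-sided exact permutation p = 0.0963). Genes are not independent replicates, so the test regrouped mice. Without the split the covariance was -0.333, against -0.0738 simulated from the shared vehicle mice alone, a difference of -0.259. The correlation across genes was -0.567, and -0.478 in the simulation. The simulation held no model effect, whose variance across genes was 2.22 in the data. Its correlation is therefore no benchmark for -0.567. Of the genes changed in the model, 81% differed the opposite way with antibody under the split and 88.2% without it. These genes were chosen with all vehicle libraries. The simulated share was 65.9%, but with no model effect to choose genes by, so it sets no level for these shares. Without vehicle replicate 1, whose position of 0.819 was the lowest of the vehicle mice, the split covariance was -0.412 (exact p = 0.0303). Without vehicle replicates 3, 4 and 6 it was -0.159 (exact p = 0.277), -0.171 (exact p = 0.247) and -0.169 (exact p = 0.24). These omissions were chosen after seeing the data.

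Antibody against regular diet showed the state of the liver under treatment. Col1a1 rose by a log2 fold change of 4.75 ± 0.37 (SE; adjusted p = 2.31e-08), Timp1 by 6.00, Spp1 by 4.29, Trem2 by 4.21, Tnf by 4.43, Mki67 by 3.26, Krt19 by 3.07 and Afp by 2.17. Acta2 passed at 1.77 (adjusted p = 0.0403), but not without antibody replicate 5 (1.21, adjusted p = 0.0824), which was at 4140 with the other 5 mice at 308 to 613, nor with quantile normalization (adjusted p = 0.109). The call also ended without any 1 of antibody replicates 1 and 2 or regular diet replicates 2, 3 and 5 (adjusted p from 0.0555 to 0.132). It ended too with no filter, only the groups compared, the replicate block and voom, so it is weak. Cdkn1a rose by 1.02, while Hes1 (0.07), Cyp7a1 (0.33) and Cldn1 (-0.76 ± 0.38) did not pass (adjusted p = 0.869, adjusted p = 0.613 and adjusted p = 0.12). In total 7247 genes changed, 4613 higher and 2634 lower. With the same total per library 7063 rose and 831 fell, with a shift of 0.44, and with quantile normalization 3553 rose and 3725 fell, with a shift of -0.39. Of 25 cholesterol synthesis genes 6 fell and 1 rose (camera adjusted p = 0.1), and of 20 hepatocyte markers 5 fell and 1 rose (camera adjusted p = 0.00206; adjusted p = 0.506 with an estimated correlation). Camera called 34 of 49 lists, and 0 with an estimated correlation. That a list passed against regular diet in only the vehicle or the antibody mice was not itself tested beyond the comparison of antibody with vehicle.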

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

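The tests of the library code, of a single library, of regroupings with library weights, of the split with the most genes, of the Mup family and of the share of blood and pancreas genes were chosen after the results were seen.

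In 139 groups of 5 or 6 libraries, over 42 genes and 6 library measures, 11 held a library far from the others by the gap over the range, where chance gives about 7. Only panel genes and the genes with the largest changes or smallest p were examined, not the further list members. Cldn1 was 2430 in antibody replicate 5, against 3860 to 5040 in the other antibody mice. Col1a1 was 2300 in vehicle replicate 1, against 6700 to 10800. Acta2 was 4140 in antibody replicate 5, against 308 to 613. Sult1e1 was 211 in antibody replicate 6, against 1020 to 2010. Ifitm6 was 51.9 in antibody replicate 2, against 23.8 to 30.6. Atg9a was 3520 in regular diet replicate 2, against 3930 to 4080. The 10 most abundant genes took 12.7% of the total in antibody replicate 1, against 9.75 to 10.8%. In regular diet replicate 1, Trem2 was 310 against 187 to 212, Hsd3b5 was 37800 against 9450 to 14100, the deposited total was 74.6 M against 48.2 to 51.2, and the second principal component was 122 against -50.7 to -40.7.

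For genes changed between vehicle and regular diet chance was excluded, as 1 of 100 splits of the mice, the real one, reached 9400 genes, with 8343 the highest of the others. For antibody against regular diet it was excluded too, at 1 of 100 (7247 genes, highest other 4745). For antibody against vehicle all 100 splits reached the real count of 0, and another split called 4941 genes, although only 2 of the other splits called any. That split had 5 of the 6 libraries with codes up to 30 on the same side, and it also parted the mice on the axis from regular diet to treated mice (means 0.89 and 1.11). The next split, with 1827 genes, did so equally (0.899 and 1.1) with 4 of the 6 on the same side. Both splits were picked because they called genes, so no cause was read from how they parted the mice. The 33 lists of vehicle against regular diet were reached by 24 of 100 splits, the real one included (highest other 38), so chance was not excluded by that count. The count cannot decide the question, since uneven splits of these mice keep part of the model difference. Most splits called many lists at the preset correlation (median 26). All 33 lists also passed fry, with adjusted p of at most 0.0021. Fry passed 38 of the 49 lists in a comparison where 9400 of 18624 genes changed. Claudins and tight junction genes passed it as well (fry adjusted p = 0.000665, camera adjusted p = 0.586). Fry thus says that members changed, not that they changed more than other genes. With library weights the 5310 genes of antibody against vehicle were reached by 8 of 100 splits (highest other 8159), so chance could not be excluded there either.

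The pattern a reader would most want to follow is the 29 lists that passed camera between antibody and vehicle, with metabolic lists higher and matrix and immune lists lower. Of these, 0 passed with an estimated correlation (smallest adjusted p = 0.161) and 0 with fry (smallest adjusted p = 0.0865). With any library left out, at least 23 of the 29 lists kept their direction and 0.5 of their median, which argues against a single library as the whole source. It cannot show whether a few mice carried the pattern. On the axis from regular diet, only vehicle replicates 3, 4 and 6 lay above all antibody mice. Genes with an unadjusted limma p under 0.05 numbered 741, 680 and 758 without each of these, where 931 were expected. They numbered 3179, 2242 and 1720 without vehicle replicates 1, 2 and 5. A term for the library code left 32 lists called, but each code level held 3 mice of either group, so that term decides nothing. Chance could not be excluded, as 32 of 100 splits called as many lists (highest other 38). A higher share of hepatocytes with antibody would lower the markers of all other cell types alike, and their differences, with a range of 0.46 over 13 lists, gave an exact permutation p = 0.835, so a change in cell shares and a change within cells cannot be told apart with these bulk values. An effect of the antibody stays among the open explanations.

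Regular diet replicate 1 had 7992 genes at least 2-fold from the mean of the other regular diet libraries, where the others had 1459 to 1556. Gene length and GC content explained 16% of the variance of its deviation, and after quantile normalization its gap over the range was 0.901 against a critical value of 0.71, which argues against either as the whole cause. For neighbouring tissue or blood, a bound of 1 set beforehand was met by pancreas (list deviation 2.064, 3 members measured), blood (1.683) and mesothelium markers (1.302). The bound was not specific to such tissue. Neutrophils (1.641), oxidative phosphorylation (1.399), pan-macrophage markers (1.198), antigen presentation (1.127), acute phase proteins (1.055) and myofibroblast markers (1.037) met it too. Lrrn4 (27) and Adipoq (2.46, the worth of 1 fragment) lay within the range of the other libraries. Upk3b (187 against 17.5 to 154) lay above it, and Prss2, Cpa1 and Pnlip were at 0. A 0 here can be a failed estimate and Adipoq was at the floor, so these genes leave such tissue open. As listed, blood and pancreas genes were too scarce to be the whole source. Globin and pancreas genes held 0.0504% of the total, a share that failed estimates would lower, and Hbb-bs was 21300 against 3010 to 5630. Its 78 ribosomal protein genes had a median deviation of 1.88, and Fos was 66.3 against 858 to 6880. No biological explanation was tested, since the design gives none for a single mouse.

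In regular diet, 11 Mup genes between 60066469 and 61674136 on chromosome 4 were listed at 0 in every library and above 0 in all others. All 15 Mup genes and pseudogenes that were tested and not at 0 throughout regular diet were lower in vehicle, 13 past the threshold. A candidate explanation is that the zeros were failed estimates over reads shared between near-identical genes, and 15 of 15 is compatible with a family most abundant in regular diet but does not show that estimates failed. Reads that were assigned to other family members, and the settings that the authors used, stay open.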

How the results depend on the processing

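The alternatives with voom, without genes of failed estimates, with the same total per library for lists and covariance, and without each vehicle library for the covariance were chosen after seeing the data. Vehicle against regular diet stayed within 1.5 times its count of 9400 in every setting run, from 6281 with a 2-fold minimum to 13193 with library weights, and from 8486 to 10680 with a library left out. The genes called were less stable than their count. Quantile normalization called 9670 genes and kept 7051 of the 9400, and the same total per library called 10633 and kept 6835. Antibody against regular diet was 11344 with library weights (6161 higher, 5183 lower) and 4778 with a 2-fold minimum, which fewer genes can pass by construction, and 6342 to 9028 with a library left out, highest without regular diet replicate 1. Antibody against vehicle stayed at 0 with every library left out and in all settings except 2. It was 5310 with library weights, where the weights ran from 0.0851 for regular diet replicate 1 and 0.175 for vehicle replicate 1 to 2.53 for antibody replicate 4. It was 2 with no filter (Gm37170 and Gm19026, vehicle means 1.88 and 0.941, all antibody values 0), genes too low for the filter. The cause of the rise with weights was not tested beyond the regroupings.

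Lists called fell to 0 with an estimated correlation in both comparisons, and to 0 with fry for antibody against vehicle. Otherwise they ranged from 32 to 38 for vehicle against regular diet and from 25 to 34 for antibody against vehicle, lowest with a library left out, at 27, without vehicle replicate 6 and without antibody replicate 3. The covariance was -0.596 over genes changed on the vehicle libraries of each split part (4639 to 9339 genes, no p computed), a set with larger model effects by construction, and ranged from -0.412 (exact p = 0.0303, without vehicle replicate 1) to -0.159 (without vehicle replicate 3) with a library left out. Under all other settings with a test its exact p lay between 0.0628 and 0.277. Quantile normalization reversed Ighd, vehicle against regular diet (-0.088, adjusted p = 0.799, from 0.69) and the set test of fatty acid oxidation and PPAR-alpha targets (median -0.128, adjusted p = 0.984, from -0.709). The cause was not tested.

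No pairing by replicate number was assumed, since same-numbered vehicle and antibody mice had correlations from -0.202 to 0.656, above 0.1 in 2 of 6, and 1 of 6 matched best with its own number. Regular diet and antibody mice had -0.0501 to 0.586 (above 0.1 in 3 of 5, 1 best with its own), and regular diet and vehicle mice -0.344 to 0.0218. With the replicate block, 9188 genes (5393 higher, 3795 lower), 0 and 6971 were called in the 3 comparisons, and 34 and 30 lists in vehicle against regular diet and antibody against vehicle. In settings other than a library left out, 2195 values of named genes were recomputed for vehicle against regular diet. Of these, 2155 kept direction and side of the threshold, 34 lost the call and 4 gained one. In antibody against vehicle 1331 of 1422 kept both and 85 gained a call. All 85 gains came with library weights, where 8 of 100 regroupings called as many genes as the real groups. With a library left out, 1820 of 1859 kept both in vehicle against regular diet and 37 lost the call, and 1212 of 1224 kept both in antibody against vehicle. Estimated depth was 27.7 to 59.5 M fragments, so genes near the minimum of 10 rest on few fragments, and simulated 1.5-fold changes were recovered in 7.46% of genes for antibody against vehicle.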

Other observations

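The comparisons of library codes, of H19 and Igf2 and of the spread between mice were chosen after the data were seen. Genes that differ between male and female mouse liver shifted in these male mice. Of 20 male-biased genes 16 fell in vehicle against regular diet and 2 rose, with a list median of -2.88, Elovl3 at -6.89 and Cspg5 at -3.43 (camera adjusted p = 1.01e-06; adjusted p = 0.265 with an estimated correlation). Mup1, counted among those that rose, was listed at 0 in all regular diet libraries. Of 22 female-biased genes 15 rose and 4 fell, with Cyp2b9 at 6.98, Lpl at 3.74 and Cyp2c40 at -3.29 (camera adjusted p = 0.0057; adjusted p = 0.265 with an estimated correlation), and the list no longer passed with the same total per library (adjusted p = 0.16). With antibody the male-biased list had a median of 0.95 against vehicle (camera adjusted p = 2.22e-07; adjusted p = 0.511 with an estimated correlation), with Cyp2d9 at 14500 ± 3920 against 8140 ± 6220 and C6 at 13600 ± 3880 against 8410 ± 6800. The female-biased list did not pass (-0.11; camera adjusted p = 0.351). Cyp2b, Cyp2c and Cyp2d genes have close paralogs, so single members are uncertain.

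Clock genes went both ways in vehicle against regular diet, with 8 higher and 7 lower of 20, Bhlhe41 at 4.25 and Cry1 at -1.78, and a set test that pointed down while the median was 0.38 (camera adjusted p = 0.945). Against vehicle the antibody median was 0.29 (camera adjusted p = 0.0503; called higher with the same total per library, adjusted p = 0.0354). Neighbouring tissue and blood markers did not pass in either comparison at the deposited scale. In vehicle against regular diet the medians were -0.75 for erythroid and blood genes (adjusted p = 0.131), 0.59 for mesothelium (0.198), 0.49 for adipocytes (unadjusted p = 0.6) and -0.61 for the 3 pancreas genes measured (0.477). With antibody against vehicle they were -0.39 (0.351), 0.22 (0.416), 0.16 (0.219) and 0.03 (0.545). With the same total per library the erythroid list passed in vehicle against regular diet (-0.15; adjusted p = 0.0318), and the pancreas median was above 0, and with antibody against vehicle it was -0.15.

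H19, an imprinted RNA of fetal liver that returns in injured and tumorous liver, was 12.2 to 18.4 in regular diet and rose in vehicle (log2 fold change 6.21; adjusted p = 7.74e-05). It differed widely between mice, at 174, 252, 4804, 7073, 533 and 4701 in vehicle replicates 1 to 6 and at 728, 129, 319, 91.7, 895 and 4894 in antibody replicates 1 to 6. Antibody against vehicle did not pass for H19 (-1.38 ± 0.98; adjusted p = 0.718). Igf2, its imprinted neighbour, was at 376 ± 381 in vehicle and 76.9 ± 35.5 in antibody (-1.21 ± 0.79; adjusted p = 0.697). The spread between mice was larger in vehicle for Trem2 (SD 3620 against 301 in antibody) and larger in antibody for Sox9 (373 against 149). Acta2 had a larger SD in antibody (1520 against 187) owing to replicate 5, at 4140 with the other antibody mice at 308 to 613. The mean log2 value of every marker list had a larger SD in vehicle, such as 0.711 against 0.179 for pan-macrophage markers. So did the first principal component (43 against 18.3), though not the second (39 against 43.8). The difference in spread was not tested.

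Library codes, whose meaning is not given in the sources used here, split the treated mice. Codes up to 30 covered replicates 1 to 3 of vehicle and of antibody, and codes from 36 covered replicates 4 to 6. The second principal component, with 15.9% of the variance, averaged 34.6 (-19.9 to 75.8) in the lower codes and -25.1 (-50.9 to -5.51) in the higher (two-sided exact permutation p = 0.00649). Of the 29 lists called between antibody and vehicle, 28 had the same direction within the lower codes and 29 within the higher, with 0 genes called in either. Several medians lay near 0 in the lower codes and not in the higher, at -0.042 and -0.619 for stellate cells, -0.033 and -0.683 for endothelial cells, -0.059 and -1.086 for neutrophils and 0.039 and -0.708 for pan-macrophage markers. The antibody effects of the code levels had a correlation of 0.298 across genes, which are not independent replicates.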
